A study of Mus musculus with 4 samples.

How the data were processed

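RNA was profiled in 4 libraries of LSK cells, the bone marrow fraction negative for lineage markers and positive for Sca-1 and Kit that holds hematopoietic stem cells and multipotent progenitors. Per the labels' protocols, the cells were sorted by flow cytometry from 8 wild-type C57BL/6 mice and 8 heterozygous for an Asxl1 frameshift knock-in, aged 8 weeks, and total RNA was reverse transcribed and made into libraries for Illumina sequencing. The design text names messenger RNA, and whether RNA was selected by its poly(A) tail was not stated in the sources used here. The labels gave 2 wild-type (WT) and 2 knock-in (KI) libraries, numbered 1 and 2 in each group. The labels did not say whether these came from separate animals or pools. The p-values of the tests of single genes thus measure the spread between these libraries, which may be technical.

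Reads were aligned and quantified with TopHat and Cufflinks on mm10 (GRCm38), per the submitters' processing notes; versions and settings were not given in the sources used here. The deposited table held 1 row per RefSeq transcript, 18691 in all, of which 17534 had coding and 1157 noncoding accessions, under 13749 gene symbols. The authors' FPKM values (fragments scaled to transcript length and library size) were given for each library. No value of 0 occurred among them, and the lowest was 1e-06 in each library. The values may thus be of transcripts above 0 in every library only, in which case genes silent in a library or a genotype could not be tested. The authors also deposited normalized log2 values for each library, with group means and SDs; the method was not given in the sources used here, and in the values each library had the same quantiles while the difference between the libraries numbered 1 and 2 was removed. A deposited comparison of KI with WT held a signed fold, a t statistic (a score), p-values and Benjamini-Hochberg adjusted p-values per transcript. Recomputing these from the deposited log2 values with a test that allows unequal variances gave the same p-values within 3.5e-12. Fragment counts were not used here, and low FPKM values showed no steps of whole reads, so that the depth of each library is unknown and no counting interval is given.

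FPKM values were summed per gene symbol. Genes with a mean FPKM of at least 1 over the 4 libraries entered the tests, 11083 genes, and 2666 were left out. Values were analysed as log2(FPKM + 1), which understates the change of low genes. KI was compared with WT with limma 3.58.1 in R 4.3.3, with a prior variance that follows the mean, genotype as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The unit in the table was per transcript, where a table per gene had been assumed, hence the summing. Of 47 gene lists written before the data were examined, 43 had at least 5 tested members and were tested with limma's camera with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists at 0.05. Camera compares the genes of a list with the other genes, so that its p-values rest on a spread over genes and not over libraries. The lists covered stem and progenitor cells, blood lineages, mature cells that a sort could carry over, the cell cycle, Polycomb complexes, signalling, metabolism and RNA quality. Of the symbols in them, 7 were matched through synonyms of the RefSeq gene table for GRCm38.p6, which also gave positions for 11067 of the tested genes.

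The tests were checked on simulated data with 200 changed genes among 11083 and 5 draws for KI against WT. The spread of each gene came from the fit with the library number as a term, after limma had drawn it toward that of other genes. Spreads were thus more alike between genes than in the data, and the shares recovered may not hold for these libraries. With the difference between library numbers simulated, the test on genotype alone recovered 0% of genes changed by 1 on the log2 scale and 0% of those changed by 2. Without that difference it recovered 97.8% and 100%, with 22.6 unchanged genes called per draw. With the difference simulated and the library number as a term, limma recovered 98.8% and 100%, with 39.8 unchanged genes called per draw. Without WT replicate 1, the test on genotype alone recovered 3% and 93%, with 6.6 unchanged genes called per draw. Camera recovered 25 of 25 lists shifted by 0.5 and called 0 lists on average where none was shifted, with genes simulated as independent.

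Tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from alternatives named as added later. The rule took Asxl1 and its partner genes, up to 12 called genes per direction, filled where fewer passed with the smallest unadjusted p up to 8 per direction, up to 4 members with the smallest unadjusted p from each list described, and the genes called in the authors' deposited table. Cdkn2a was among the genes to be named and is not analysed here, which says nothing about its level. Gene models and receptor segments were counted but not named. The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, quantile and median scaling, limma without trend or with robust priors, a log2 threshold of 1, an adjusted p of 0.1, each library left out, the library number as a block, and list tests with an estimated correlation, on ranks or by rotation (fry). Chosen after seeing the data were transcripts tested singly, the authors' normalized values with and without the block, and an estimated correlation with the block. Genes with near-identical copies, among them histone genes, Ly6c2, Hba-a1 and the ubiquitin gene Ubb, can share reads, and Cufflinks divides reads between them, so that their values are uncertain.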

Results

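Gene expression was measured by RNA sequencing in LSK cells of wild-type mice and of mice heterozygous for a frameshift knock-in allele of Asxl1, which encodes a chromatin protein that works with Polycomb-group and BAP1 complexes and is mutated in myeloid malignancies. There were 2 libraries per genotype. The listed FPKM summed to 337313 in WT-1, 402754 in WT-2, 324255 in KI-1 and 411542 in KI-2, and the 10 most abundant genes held between 6.78% and 7.58% of it. The sequencing depth is unknown. Values below are means ± SD over the 2 libraries of a group.

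The comparison of KI with WT asks what a single mutant Asxl1 allele changes in the stem and progenitor compartment. Asxl1 itself, at chromosome 2, 153345830 to 153404007 (GRCm38), stood at 20.8 FPKM in WT-1, 18.8 in WT-2, 22.2 in KI-1 and 19.1 in KI-2. The group means were 19.8 ± 1.39 in WT and 20.7 ± 2.23 in KI (SD, n = 2), a log2 fold change of 0.057 with SE 0.21. An exact two-sided permutation test gave p = 0.667, where 0.333 is the smallest p that 2 against 2 libraries allow. A frameshift need not alter the level of an mRNA, so that this value checks the genotype labels only weakly. The sign turned without WT replicate 2, at -0.011, and without KI replicate 1, at -0.049. None of the partner genes was called by limma (adjusted p = 1), with Asxl2 at 8.33 ± 0.144 and 9.53 ± 1.66 FPKM, the deubiquitinase gene Bap1 at 26.2 ± 6.33 and 25.6 ± 3.92, Foxk2 at 14.6 ± 0.961 and 17.7 ± 2.96, and Mbd6 at 39.4 ± 7.56 and 33.9 ± 2.85 in WT and KI. As a list, the 11 ASXL and BAP1 genes were not called by camera (adjusted p = 0.426).

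No single gene passed the test between KI and WT, while lists of granulocyte-monocyte, B-lineage and lymphoid-primed genes rose and lists of stem cell, histone and immediate early genes fell as groups in camera with a preset correlation. With an estimated correlation, in a test that was not simulated, camera gave each of these lists an adjusted p of 0.966. All of them but the granulocyte-monocyte list lost its call or turned its direction without at least 1 of the 4 libraries. Leaving out 1 library unbalances the library numbers between the genotypes, so that part of the difference between the numbers enters. With the library number as a term, all 13 lists called by camera with a preset correlation kept their call. The 8 genes higher in KI with the smallest unadjusted p are given as values; that choice favours genes whose groups do not overlap. Csf1r, the receptor for macrophage colony-stimulating factor, stood at 4.06 ± 0.737 FPKM in WT and 9.27 ± 2.51 in KI (SD, n = 2). Irf8, a transcription factor of monocyte and dendritic cell development, stood at 31.3 ± 3.43 and 52.4 ± 8.44. Ms4a3, a granulocyte-monocyte progenitor marker, stood at 1.96 ± 0.612 and 4.47 ± 0.441, and Ly86, a partner of a Toll-like receptor relative, at 5.28 ± 1.70 and 12.02 ± 0.933. Ly6c2 stood at 12.7 ± 8.07 and 35.1 ± 12.9, the cytokine gene Osm at 9.62 ± 1.26 and 17.3 ± 1.14, Evc at 1.37 ± 0.719 and 4.02 ± 1.09, and Myl4 at 0.848 ± 0.738 and 2.80 ± 0.0368.

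On the lower side, Atp10d, annotated as a transcribed pseudogene in GRCm38, had the smallest unadjusted p of all (0.00104, limma), with 7.10 ± 1.26 FPKM in WT and 1.90 ± 0.0964 in KI, a log2 fold change of -1.48 with SE 0.25. The polyubiquitin gene Ubb stood at 1068 ± 65.0 and 485 ± 154 FPKM. Hmga2, a chromatin protein gene linked to stem cell self-renewal, stood at 2.94 ± 0.456 and 1.26 ± 0.0230. The microRNA gene Mir8094, which lies inside Ddx39b on chromosome 17 and can share its reads, stood at 88.5 ± 44.0 and 30.6 ± 16.5. Efcab7 stood at 6.05 ± 1.02 and 2.97 ± 0.239, the troponin gene Tnni3 at 8.79 ± 0.0196 and 4.63 ± 1.02, the chloride transporter gene Clcn3 at 5.29 ± 0.849 and 2.54 ± 0.330, and the histone gene Hist1h2bf at 2.13 ± 0.653 and 0.623 ± 0.247.

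Of 11083 genes tested with limma, 0 passed an adjusted p of 0.05, and all 16 genes above had an adjusted p of 1 in this fit on genotype alone. At an unadjusted p under 0.05 there were 47 genes, 26 higher and 21 lower in KI, against 554 by chance in a fit whose residual spread holds no other difference. Here that spread holds the difference between libraries numbered 1 and 2, described below, and in simulated data with that difference this test recovered 0% of genes changed by 2 on the log2 scale, so that a count of 0 does not show that genes were alike. With the library number as a term, limma called 1 gene, Mir8094 (log2 fold change -1.52, SE 0.076, adjusted p = 0.026), and 787 genes had an unadjusted p under 0.05, 402 higher and 385 lower, while in simulated data that fit called 39.8 unchanged genes per draw beside 200 changed ones. In KI, 52.1% of tested genes were higher, but 27.5% without WT replicate 1, 71% without WT replicate 2, 71.8% without KI replicate 1 and 30.6% without KI replicate 2. The groups did not overlap for 1491 genes, or 13.5%. Chance would give 33.3% if the 4 libraries were exchangeable, but the difference between the numbers lowers that share too. The fits without 1 library leave the library numbers unbalanced between the genotypes, so that part of the difference between the numbers enters them. Their called genes and shares of higher genes thus do not measure genotype alone. In simulated data with that difference, the fit without WT replicate 1 called 6.6 unchanged genes per draw beside 200 changed ones.

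**Figure D1:**
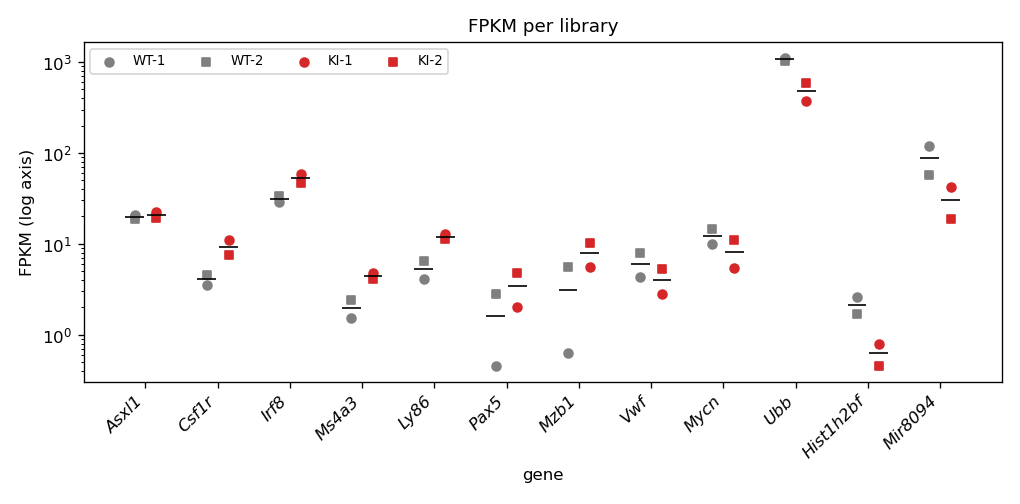
FPKM (log axis) of 12 named genes in each library, with WT in grey, KI in red, circles for number 1, squares for number 2 and a black line at each group mean. Csf1r stood at 3.54 and 4.58 in WT and 11.04 and 7.50 in KI, Ubb at 1114 and 1022 in WT and 376 and 594 in KI, and Asxl1 between 18.8 and 22.2 in all 4 libraries.

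The libraries differed far more by number than by genotype. Across genes, Spearman's correlation was 0.984 between WT-1 and KI-1 and 0.992 between WT-2 and KI-2, against 0.963 and 0.966 within a genotype, genes not being independent replicates. Between the libraries numbered 2 and 1, limma called 4452 genes, 3942 higher and 510 lower, and the log2 fold changes had an SD of 0.397 against 0.195 between genotypes and a median of 0.271. This fit did not rescale the libraries. The median log2(FPKM + 1) of tested genes was 3.51 in WT-1 and 3.53 in KI-1, against 3.78 in WT-2 and 3.77 in KI-2. A difference of scale thus enters the count of called genes and its direction. Chosen after their values were seen, the immediate early gene Fos stood at 1890, 706, 950 and 566 FPKM in WT-1, WT-2, KI-1 and KI-2, and the X-inactivation RNA Xist at 92.5, 35.0, 103 and 53.3. The labels give no batch, so the difference between KI and WT within each number is set beside each list below. Values below from fits without 1 library hold part of the difference between the numbers, which such fits leave unbalanced between genotypes.

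Of 43 lists tested with camera, 13 were called, 8 up and 5 down, and 30 were not. Camera's p-values with the preset correlation rest on a spread over genes and not over libraries, so that a small one does not measure agreement between libraries. With an estimated correlation between genes, no list was called, each having an adjusted p of 0.966. That test also called 0 lists between the numbers. Camera sets a list against the other genes, so that a shift shared by most genes does not count. The 4452 genes that limma called between the numbers therefore do not show that this test missed lists there. The test was not simulated, and its result does not show that a list was alike between genotypes. In every list, 0 members passed over all genes tested and 0 passed adjusted over the list alone in the fit on genotype alone. With the library number as a term, 0 members again passed over all genes tested, while some passed adjusted over the list alone. These were 10 granulocyte-monocyte, 6 B cell, 2 lymphoid-primed, 1 monocyte, 1 dendritic cell and 1 mast cell genes higher in KI, and 6 histone and 1 HSC-enriched genes lower. Notch genes (1 higher, 1 lower), erythroid genes (1 and 2) and cyclin-dependent kinase inhibitor and senescence genes (1 and 1) passed on both sides. False calls in adjustment over a list alone were not simulated. Splitting the 4 libraries in other ways called as many or nearly as many lists, 19 between the numbers and 12 for WT-1 and KI-2 against WT-2 and KI-1. Lists called between the genotypes and by neither other split were those of lymphoid-primed, megakaryocyte, G1/S and type I interferon genes. Camera also called the HSC-enriched (adjusted p = 0.0475) and B cell (0.0251) lists between the numbers. For WT-1 and KI-2 against WT-2 and KI-1 it also called the monocyte (0.0165) and dendritic cell (0.0224) lists.

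Granulocyte-monocyte progenitor genes rose in KI, with a median log2 fold change of 0.461 over 19 genes (camera adjusted p = 7.04e-16; 0.966 as adjusted p with an estimated correlation). Their median was 0.707 in number 1 and 0.244 in number 2, and 13 of the 19 genes were higher in both. Besides Ms4a3, Irf8 and Ly6c2, the neutrophil protease gene Ctsg stood at 35.0 ± 3.06 FPKM in WT and 57.5 ± 10.1 in KI. The 16 members in no other called list had a median of 0.431. This list kept its call without each library, but was also called by both other splits, for WT-1 and KI-2 against WT-2 and KI-1 (adjusted p = 0.000754) and, lower in number 2, between the numbers (0.0286). Monocyte and macrophage genes rose by a median of 0.171 over 11 genes (adjusted p = 0.000287), with 0.232 in number 1 and 0.0925 in number 2. They share Ly6c2 and Lyz2 with the progenitor list and Csf1r with the lymphoid-primed list. Dendritic cell and MHC class II genes rose by 0.206 over 12 genes (adjusted p = 0.000735), with 0.200 and 0.0829 within the numbers, and H2-Aa stood at 22.3 ± 6.07 and 30.3 ± 0.354 FPKM and Cd74 at 81.2 ± 16.4 and 105 ± 15.5. The dendritic list shares Irf8 with the progenitor list, Flt3 and Tcf4 with the lymphoid-primed list and Bst2 with the interferon list, so that these lists are not separate. With an estimated correlation, the monocyte and dendritic lists both had an adjusted p of 0.966. Without WT replicate 1 both calls were lost, with camera adjusted p = 0.0526 and a median of 0.0102 for the monocyte list and 0.351 for the dendritic list, whose median turned to -0.0845.

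Genes of the lymphoid path rose as well. B cell genes had a median log2 fold change of 0.517 over 12 genes (camera adjusted p = 1.17e-05), with 0.344 in number 1 and 0.653 in number 2, and 9 of the 12 were higher in both. Mzb1 stood at 3.13 ± 3.53 and 7.94 ± 3.36 FPKM in WT and KI, Pax5, the factor that commits cells to the B lineage, at 1.62 ± 1.66 and 3.40 ± 1.97, and the surrogate light chain gene Vpreb1 at 4.25 ± 3.78 and 10.7 ± 9.46. Multipotent and lymphoid-primed progenitor genes rose by a median of 0.114 over 23 genes (adjusted p = 0.000738), with 0.162 and 0.0619 within the numbers. Dntt, which adds bases at receptor gene junctions, stood at 21.6 ± 1.36 and 31.7 ± 10.3 FPKM, Il7r at 3.28 ± 0.657 and 4.99 ± 1.74, and Blnk at 6.62 ± 2.05 and 9.32 ± 3.63. The lists share 3 genes, Ebf1, Igll1 and Blnk, and both had an adjusted p of 0.966 with an estimated correlation. Camera's adjusted p for the B cell list was 0.229 without WT replicate 1 and 0.946 without KI replicate 2, where its median was -0.157, and that for the lymphoid-primed list was 0.0595 without WT replicate 1, with a median of 0.000249.

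HSC-enriched genes fell in KI, with a median log2 fold change of -0.199 over 39 genes (camera adjusted p = 1.16e-06; 0.966 as adjusted p with an estimated correlation). The median was -0.199 in number 1 and -0.185 in number 2, and 30 of the 39 genes were lower in both. The stem cell marker Clca1 (Entrez 12722) stood at 6.17 ± 2.23 FPKM in WT and 3.69 ± 1.30 in KI, Mycn at 12.3 ± 3.29 and 8.18 ± 3.83, Trim47 at 12.3 ± 3.62 and 8.83 ± 3.87, and Vwf, which marks platelet-biased stem cells, at 6.07 ± 2.53 and 4.03 ± 1.69. Megakaryocyte genes, which share 3 members with this list, fell, with a median of -0.146 over 19 genes (adjusted p = 0.0204), with -0.143 and -0.0808 within the numbers and an adjusted p of 0.966 with an estimated correlation. Sdpr stood at 5.63 ± 2.84 and 3.30 ± 0.629 FPKM, while Thbs1 stood higher in KI, at 18.4 ± 5.12 and 34.7 ± 19.3. The stem cell call was lost without WT replicate 2 (adjusted p = 0.271, median 0.0714) and without KI replicate 1 (0.21, median 0.0202), and the megakaryocyte call without the same libraries (0.552 and 0.875) and with no filter (0.0649).

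Replication-dependent histone genes fell, with a median log2 fold change of -0.492 over 37 genes (camera adjusted p = 6.31e-12), with -0.770 in number 1 and -0.126 in number 2, and 25 of the 37 were lower in both. Hist1h2bc stood at 66.5 ± 25.4 and 38.6 ± 1.97 FPKM in WT and KI, Hist1h2bg at 25.03 ± 1.88 and 17.1 ± 3.44, and Hist2h2bb at 4.13 ± 3.65 and 0.951 ± 0.563. Immediate early genes, which cells induce within minutes of a stimulus, fell, with a median of -0.278 over 28 genes (adjusted p = 0.00364), with -0.656 in number 1 and 0.0083 in number 2. Klf6 stood at 299 ± 264 and 105 ± 31.1 FPKM and Dusp1 at 323 ± 218 and 162 ± 55.2, while Fosl2 stood higher in KI, at 17.2 ± 0.0839 and 28.3 ± 9.21. Both lists had an adjusted p of 0.966 with an estimated correlation and were also called by both other splits. Their direction turned without WT replicate 1, with medians of 0.368 for histone genes and 0.136 for immediate early genes. Without KI replicate 2 the histone median was 0.0318 and the immediate early call was lost (adjusted p = 0.272), as it was under quantile scaling (0.133), median scaling (0.129) and no filter (0.103).

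Cell cycle and growth genes rose by small amounts. The median log2 fold change was 0.0991 over 41 G1/S and DNA replication genes (camera adjusted p = 0.00197), with 0.0717 in number 1 and 0.144 in number 2, and Fen1 stood at 25.5 ± 8.80 and 33.2 ± 8.25 FPKM and Ccne2 at 4.72 ± 0.614 and 5.83 ± 0.901. It was 0.0684 over 45 G2/M and mitosis genes (adjusted p = 0.00859), with -0.0089 and 0.188, and Ccnb1 stood at 15.4 ± 0.709 and 19.9 ± 0.0635 and Aurkb at 26.2 ± 0.671 and 33.1 ± 0.754. Ribosome biogenesis and MYC target genes rose by 0.129 over 33 genes (adjusted p = 0.00197), with 0.0477 and 0.182, and Srm stood at 32.0 ± 4.73 and 39.7 ± 9.65 and Nolc1 at 59.9 ± 0.619 and 68.9 ± 0.941. Type I interferon response genes fell, with a median of -0.0745 over 33 genes (adjusted p = 0.0277), with -0.0968 and -0.0429, and Rsad2 stood at 6.64 ± 0.456 and 4.84 ± 1.5 and Oas2 at 9.40 ± 1.26 and 7.46 ± 0.380. All 4 lists had an adjusted p of 0.966 with an estimated correlation. Camera also called the mitosis list for WT-1 and KI-2 against WT-2 and KI-1 (adjusted p = 7.71e-05) and between the numbers (1.91e-17). It called the ribosome biogenesis list in the former split too (0.0315). Without WT replicate 2, camera gave an adjusted p of 0.645 for G1/S genes, 0.834 for ribosome biogenesis genes and 0.774 for interferon genes, and the mitosis median turned to -0.078; without KI replicate 1 the values were 0.136, 0.183, 0.817 and, for mitosis genes, 0.0549. Without KI replicate 2 the G1/S and ribosome biogenesis calls were lost too (0.138 and 0.0843, with medians of -0.0187 and 0.000499), as were the mitosis call under quantile and median scaling (0.0539 and 0.0546) and the interferon call with no filter (0.0906).

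**Figure D2:**
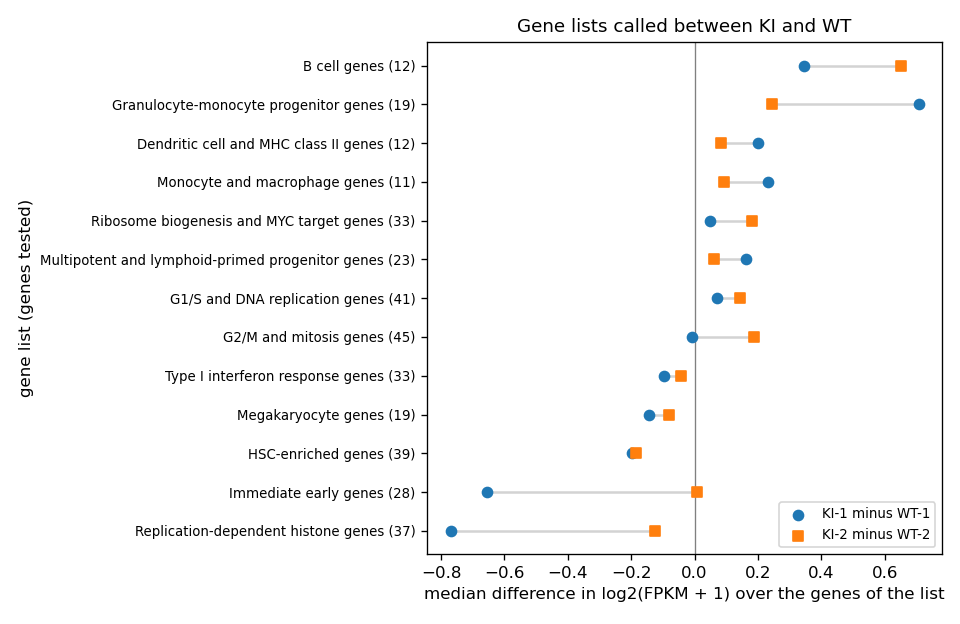
Median difference in log2(FPKM + 1) between KI and WT over the genes of each called list, within the libraries numbered 1 (circles) and 2 (squares), with the number of genes tested in parentheses. The granulocyte-monocyte list stood at 0.707 and 0.244, the HSC-enriched list at -0.199 and -0.185, and the immediate early list at -0.656 and 0.0083.

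Polycomb genes, named because Asxl1 acts with them, were not called as lists, with camera adjusted p = 0.559 for 26 genes of repressive complex 1, 0.868 for 12 of complex 2 and 0.124 for 7 HoxA genes. The list of developmental transcription factors repressed by Polycomb in blood had 2 of 71 genes past the filter, and the HoxB, HoxC and HoxD list 3 of 28. Neither list was tested, so that a rise of such silent genes was not examined. Within complex 1, Pcgf1 stood at 6.87 ± 0.276 FPKM in WT and 4.14 ± 0.109 in KI and Pcgf2 at 6.46 ± 0.286 and 3.90 ± 1.14, while Pcgf5 stood higher in KI, at 31.06 ± 0.231 and 36.4 ± 0.918; 12 of its genes were higher and 14 lower, with a median log2 fold change of -0.00803. Hoxa3 stood at 5.79 ± 0.636 and 3.81 ± 0.388 FPKM and Hoxa9 at 26.0 ± 3.47 and 22.5 ± 3.59. Cyclin-dependent kinase inhibitor and senescence genes were not called either (adjusted p = 0.94), with Cdkn1a at 26.1 ± 6.99 and 33.6 ± 10.4 FPKM and Igfbp7 at 1.04 ± 0.346 and 2.17 ± 0.700. Cdkn2a was not analysed here.

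Markers of other cells that the gate could hold were compared in the same way. The 10 mature neutrophil genes were not called (camera adjusted p = 0.426), with medians of 0.780 in number 1 and 0.0488 in number 2, and Ltf stood at 2.08, 0.110, 6.18 and 0.180 FPKM in WT-1, WT-2, KI-1 and KI-2. The sign of Ltf turned without WT replicate 2 and without KI replicate 1. Erythroid genes (13, adjusted p = 0.812), T and NK cell genes (7, 0.856), mast cell and basophil genes (7, 0.209), endothelial genes (9, 0.122) and stromal genes (5, 0.911) were not called. With the library number as a term, the endothelial list was called lower in KI (adjusted p = 0.0116), with medians of -0.104 and -0.128 within the numbers, but not with an estimated correlation as well (adjusted p = 0.79). The globin gene Hba-a1 stood at 7.23 ± 0.386 FPKM in WT and 17.2 ± 9.60 in KI.

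In the authors' deposited table, 3 of 18691 transcripts passed an adjusted p of 0.05, all lower in KI. The authors' deposited table gave a signed fold of -1.23 for Arl3, -1.11 for Cog2 and -1.44 for a noncoding transcript of Tmem176b, each with an adjusted p of 0.0473. It gave 1.03 for Asxl1, with an adjusted p of 0.451. At an unadjusted p under 0.05, the authors' deposited table held 4041 transcripts, or 21.6%, against 47 genes with limma on the FPKM values. Summed per gene, Arl3 stood at 41.2 ± 2.28 FPKM in WT and 31.3 ± 3.95 in KI, Cog2 at 8.996 ± 0.750 and 7.66 ± 0.637, and Tmem176b at 209 ± 73.4 and 195 ± 61.5, none called by limma (adjusted p = 1).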

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

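Transcripts tested singly, the authors' normalized values with and without the replicate block, and the estimated correlation with that block were chosen after seeing the data. The count of called genes stayed at 0 under both pseudocounts, both filters, both scalings, limma without trend or with robust priors, the log2 threshold, an adjusted p of 0.1, transcripts singly and the authors' normalized values, and was 7 to 37 with a library left out, where the lone library is assumed to vary like the other group. Of 50 genes called in any of those 4 fits, 1 was called in all. The libraries sharing a number deviated together (r = 0.691 across genes), but the labels do not pair them. With the replicate block, 1 gene was called, Mir8094 (log2 fold change -1.52, SE 0.076, adjusted p = 0.026), 787 genes had an unadjusted p under 0.05, and 16 lists were called, among them all 13 and those of antioxidant, endothelial and NF-kB genes. The count of lists was 0 with an estimated correlation, 0 by fry and 0 with an estimated correlation and the replicate block, and 11 to 16 elsewhere. The share of genes higher in KI was 50.8% under median scaling and 27.5% to 71.8% with a library left out, the scale of the libraries differing by number. With a library left out, the log2 fold change ranged from -0.049 to 0.162 for Asxl1, and list medians from -0.49 to 0.0714 for HSC-enriched, -1.32 to 0.368 for histone, -0.68 to 0.136 for immediate early, -0.381 to 0.0516 for megakaryocyte, -0.311 to 0.141 for interferon, -0.078 to 0.232 for G2/M, -0.0187 to 0.204 for G1/S, -0.157 to 1.19 for B cell, -0.0845 to 0.582 for dendritic cell, 0.000249 to 0.333 for lymphoid-primed, 0.0102 to 0.46 for monocyte, 0.000499 to 0.22 for ribosome biogenesis and 0.349 to 0.683 for granulocyte-monocyte genes. Each such fit leaves the numbers unbalanced between genotypes. For Bap1 the range was -0.259 to 0.22 and for Ltf -0.646 to 1.96, for Hist1h1d -2.22 to 0.23, for Fos -1.37 to 0.0543, for Xist -0.316 to 1.06, for Tmem176b -0.459 to 0.269 and for Ddx39b -0.116 to 0.172. In such a fit, part of the difference between the numbers enters that between genotypes. Genes and lists that differ by number therefore move with the library left out. No other cause of these turns was tested. The granulocyte-monocyte list kept its call in all 12 settings other than an estimated correlation and fry. Of the other values for named genes, 791 kept their side of the threshold and 12 passed it, those with a library left out or under the block. Count-based alternatives were not run, because the values are FPKM. The depth is unknown and sets no stated limit here.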

Other observations

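Tests of carried-over cells, of the immediate early response, of other splits, of S phase, of RNA without a poly(A) tail and of the authors' p-values were chosen after the result was seen; those of short transcripts, of genes near Asxl1 and of Ddx39b were set beforehand. The test of carried-over cells was first set on number 2 alone, and was extended to both numbers after its result was seen. Lists of signalling and metabolism not described above were not called by camera on genotype alone. Notch pathway genes had a median log2 fold change of 0.118 over 14 genes (adjusted p = 0.0562), antioxidant genes 0.0885 over 34 (0.0765), and NF-kB and inflammatory genes -0.102 over 24 (0.198). With the library number as a term, the antioxidant list was called higher (adjusted p = 0.0191) and the NF-kB list lower in KI (0.0442), neither with an estimated correlation as well (0.79). Cytosolic ribosomal protein genes had a median of 0.000276 over 57 genes (0.856) and nuclear oxidative phosphorylation genes 0.0239 over 67 (0.334).

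Stem cell genes were lower while granulocyte-monocyte, B-lineage and lymphoid-primed genes were higher in KI. A candidate explanation is mature cells carried over from outside the gate. The sort on lineage markers was meant to remove them, but its purity was not examined here. In number 1 the neutrophil list had a median of 0.78, near the 0.707 of the progenitor list. In number 2 it had 0.0488 (95% bootstrap interval -0.399 to 0.15 over its 10 genes), under the progenitor list's 0.244. The B cell list had 0.653 in number 2. Each number holds 1 library per genotype, so that carried-over cells stay open in both. An immediate early response stays open too: in number 2 the immediate early median was 0.0083 while HSC-enriched genes other than Egr1 had a median of -0.187 (-0.293 to -0.127), but this sets 1 library against 1 with a spread over genes alone. The 4 libraries have only 3 splits, too few for a share under 0.05; the genotypes gave 13 lists and the highest other split 19, which follows the library number, and 2 of the 3 splits gave at least 13. A shift of the sorted population toward committed progenitors in KI is a biological explanation that stays untested.

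Histone genes were lower in KI by a median of -0.492 (-0.591 to -0.336). Fewer cells in S phase would lower DNA replication genes too, and their median was 0.0991 (0.0857 to 0.125 over genes), with 0.0717 and 0.144 within the numbers. It was -0.0187 at the lowest with a library left out, in fits that leave the numbers unbalanced. Within neither number did the DNA replication genes fall with the histone genes. Each number sets 1 library against 1, and the interval is a spread over genes and not over libraries. Fewer S-phase cells in KI thus stay open. Lower recovery of short transcripts is argued against, in these libraries, by the other 243 genes with transcripts under 700 nt, whose median was -0.0135 (-0.0368 to 0.00804 over genes). Of the 37 histone genes, 22 were under that limit, so that this bears on those alone. Lower recovery of RNA without a poly(A) tail, which most histone mRNAs lack, stays open, because the small nucleolar and Cajal body RNAs tested were 5, with a median of 0.223 (-0.418 to 1.02), and whether RNA was selected by its tail is unknown. Both genotypes also differed by number in these genes; Hist1h1d, chosen after its values were seen, stood at 17.0 and 2.29 FPKM in WT-1 and WT-2 and 7.08 and 0.840 in KI-1 and KI-2.

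The authors' deposited table held 21.6% of transcripts at an unadjusted p under 0.05. In the deposited normalized values the difference between library numbers was removed, with an SD of 0.00448 over transcripts against 0.222 between genotypes. The deposited test still counted 2 libraries per group. The split of WT-1 and KI-2 against WT-2 and KI-1, which no label defines, gave 18.3% in the same values. Simulated libraries with no effect, treated alike, gave 20.3%. With the number difference removed, the split above and that of the genotypes rest on the same 2 differences, each serving as the other's spread. Like shares then follow where these differences are of similar size, so that the split was no separate test. A share of this size arises without an effect, and it does not say which transcripts differ between genotypes.

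Sequence carried along with the targeted allele might change genes around Asxl1: the 134 tested genes within 10 Mb had a median absolute log2 fold change of 0.105, at percentile 87.7 of 10000 lists matched on expression. That is under the bound of percentile 95 set beforehand, but the bootstrap interval of the median, added after the percentile was seen, is 0.0766 to 0.118 and reaches past the 0.11 at that percentile, which leaves this open. For Mir8094, which differed by -1.48 and -1.55 within the numbers, a fall of its host gene could set the value, but Ddx39b stood at 163 ± 15.7 FPKM in WT and 166 ± 23.6 in KI, a log2 fold change of 0.0281. Its 95% interval was -0.581 to 0.637 on genotype alone and, with the library number as a term, in which Mir8094 was called, -0.16 to 0.216, above the bound of -0.5 set beforehand, which argues against a fall of the host; the choice of this second fit was made after the first interval was seen. A different division of the host's reads between the 2 gene models was not tested.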
